A study of Mus musculus with 8 samples.

How the data were processed

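Gene expression was measured in splenocytes of 8 mice on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Splenocytes are the mixed cells of a digested spleen, so each value is an average over B cells, T cells, myeloid cells, red cell precursors and others. The groups were wild-type C57/B6 mice (WT, 2 mice), mice carrying the Sle1.3 lupus-susceptibility background (3 mice) and Sle1.3 mice with 1 functional copy of E2-2 (Sle1.3/E2-2het, 3 mice). E2-2 is the transcription factor encoded by Tcf4 and is required by plasmacytoid dendritic cells. Per the labels' protocols, spleens were digested with collagenase and DNase before RNA was extracted and amplified.

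The authors deposited a table of 35556 probe sets in which each value is an intensity on a linear scale. Per the submitters' processing notes, RMA and Affymetrix Expression Console were used. Neither notes nor protocols give their versions, the role of each or an annotation build. The lowest values of the arrays lay between 4.57 and 11.2 and the highest between 16650 and 20352, which is a linear range, so log2 was taken here before any test. Array quantiles differed, so the deposited values had not been brought to one distribution over all 8 arrays. No background level or detection call came with the table, and the number of arrays limits the precision. The deposited table was used as it stands, and no array was left out of the planned fit.

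Of the 35556 probe sets, 21789 were assigned to a single gene symbol, 1621 to several and 12146 to no listed gene. Probe sets with several genes or none entered no comparison. List members found only on those were not analysed here. Each of 19938 genes was represented by its probe set with the highest mean, and genes with a mean log2 intensity above the 25th percentile (5.01) were tested, which left 14953. Chromosomes were taken from the RefSeq annotation of the mouse genome by Entrez gene identifier. Families with near-identical copies (Klra, Ear, Ly6, the interferon-inducible Ifi200 genes, immunoglobulins) may share probes, so a value there can belong to a relative of the named gene.

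Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). A single fit to all 8 arrays held the group and the labelled sex, with 4 residual degrees of freedom. Adjusted p values follow Benjamini and Hochberg over the genes tested, at a threshold of 0.05. The tests, the groups, the gene lists, the rule for named genes and 14 of the alternatives were fixed before the data were examined. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 of 24 lists with at least 5 measured members. Camera with an estimated correlation and fry were run beside it. The list of sex-linked genes had 4 measured members and was not tested as a group. The lists covered interferon-stimulated genes, plasmacytoid and conventional dendritic cells, plasma cells, germinal centre B cells, B cells, T cells, T follicular helper and activated T cells, natural killer cells, neutrophils and their precursors, erythroid cells, splenic macrophages, monocytes, megakaryocytes and platelets, mast cells and basophils, stromal and endothelial cells, exocrine pancreas, the cell cycle, the unfolded protein response, dissociation stress, cytokines and chemokines, antigen presentation, genes of the Sle1 region, and sex-linked genes. Several lists share members, and most of their genes are transcribed in more than 1 cell type of the spleen.

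Named genes are those past the threshold with the largest absolute log2 difference, up to 10 in each direction. Where fewer than 5 passed, the genes with the smallest p were added up to 5 and are given as values. For each list the rule took up to 4 members that passed, or the 2 with the smallest p where none did, and Tcf4 and the sex-linked genes were always reported. Genes named outside the rule are said to have been chosen after their values were seen.

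The array values showed 2 sets of arrays and a possible pairing of same-numbered Sle1.3/E2-2het and Sle1.3 mice, neither given by the labels. Within the Sle1.3 groups labelled sex falls together with the array set, in opposite directions in the 2 genotypes. By construction, the planned difference between Sle1.3/E2-2het and Sle1.3 is then the mean of the first-set and the second-set difference, each with equal weight, and its standard error takes in the distance between the sets. Fits with the replicate number as a block, with the array set as a block, and on the first set alone are therefore printed beside it. Both WT mice are labelled male, so the labelled-sex term in the differences from WT also comes from the array sets of the Sle1.3 groups. In Sle1.3 versus WT it gives Sle1.3 replicate 3 more weight than Sle1.3 replicates 1 and 2, and it is no correction for sex. With either block and labelled sex, Sle1.3 versus WT by construction weights Sle1.3/E2-2het replicates 1 and 2 like Sle1.3 replicates 1 and 2. It also subtracts part of the second-set difference. Of these fits, only the first set alone estimates Sle1.3 versus WT without Sle1.3/E2-2het arrays. The alternatives planned were no sex covariate, a replicate block with and without sex, mice labelled male only, only the groups compared, other filters on dim genes, quantile normalization, median centring, other ways to choose probe sets, other estimates of the spread, other set tests, and leaving out each mouse. The 4 settings with the array set were added after seeing the data. For WT mice a pairing by number was unclear, since the deviations of same-numbered WT and Sle1.3 arrays correlated at -0.0768 and 0.214 across genes and those of WT and Sle1.3/E2-2het arrays at 0.151 and 0.160. The replicate block still numbers WT mice with the others, so its totals against WT rest on a pairing that was not shown.

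The limma fit was tested on simulated data with 100 genes changed at each of 2 sizes among 14953. At a log2 change of 2, it recovered 88% of the changed genes for Sle1.3 versus WT, 89% for Sle1.3/E2-2het versus Sle1.3 and 86% for Sle1.3/E2-2het versus WT. At a log2 change of 1 it recovered 30%, 58% and 45%, with 12, 19 and 12 false calls in all. The simulated noise was independent for each gene and array, without array sets or pairs. These shares therefore do not give the power of the fit on the deposited arrays.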

Results

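Splenocyte RNA from 8 mice was compared across 3 genotypes: WT (n = 2), Sle1.3 (n = 3) and Sle1.3/E2-2het (n = 3). The median log2 intensity of an array lay between 5.83 and 5.95 in 6 arrays and at 6.17 in both arrays labelled replicate 3. Those arrays, Sle1.3 replicate 3 and Sle1.3/E2-2het replicate 3, had lowest linear intensities of 10.9 and 11.2, against 4.57 to 5.11 in the other 6, and are called the second array set. The first array set held 2 mice of each genotype, and the second held no WT mouse.

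Tcf4, the gene of E2-2 on chromosome 18, had a mean log2 intensity of 8.91 ± 0.15 (SD, n = 2) in WT, 8.79 ± 0.23 (SD, n = 3) in Sle1.3 and 8.52 ± 0.63 (SD, n = 3) in Sle1.3/E2-2het mice. In the first set it was 8.18 and 8.13 in the Sle1.3/E2-2het mice, against 8.67 and 8.63 in Sle1.3 and 9.02 and 8.80 in WT. In the second set it was 9.25 in the Sle1.3/E2-2het mouse and 9.06 in the Sle1.3 mouse. The planned difference between Sle1.3/E2-2het and Sle1.3 was -0.16 (SE 0.29, adjusted p = 1.00), and the first set alone gave -0.50 (SE 0.15, adjusted p = 0.262). The replicate block gave adjusted p = 0.834. Without Sle1.3/E2-2het replicate 3 the difference was -0.90 (adjusted p = 0.0193), and without Sle1.3 replicate 3 it was 0.59 (adjusted p = 0.0627), and either omission leaves the labelled sex to the other second-set array.

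The sex-linked genes separated the mice cleanly but not always as labelled. Xist, the X-inactivation transcript of females, was 4.12 and 3.75 in the WT mice, which are labelled male, and 10.77, 10.68 and 11.90 in the Sle1.3 mice. The Y-linked genes Kdm5d (3.96 to 4.19), Uty (3.82 to 4.27) and Eif2s3y (3.02 to 3.83) were near the floor in all 3 Sle1.3 mice. Sle1.3 replicate 3 is labelled male, so its array and its label differ. In Sle1.3/E2-2het mice Xist was 3.79, 4.29 and 11.82, as labelled. By these genes Sle1.3 versus WT was also a comparison of females with males, and Sle1.3/E2-2het versus Sle1.3 compared males with females in the first set and a female with a female in the second.

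**Figure D1:**
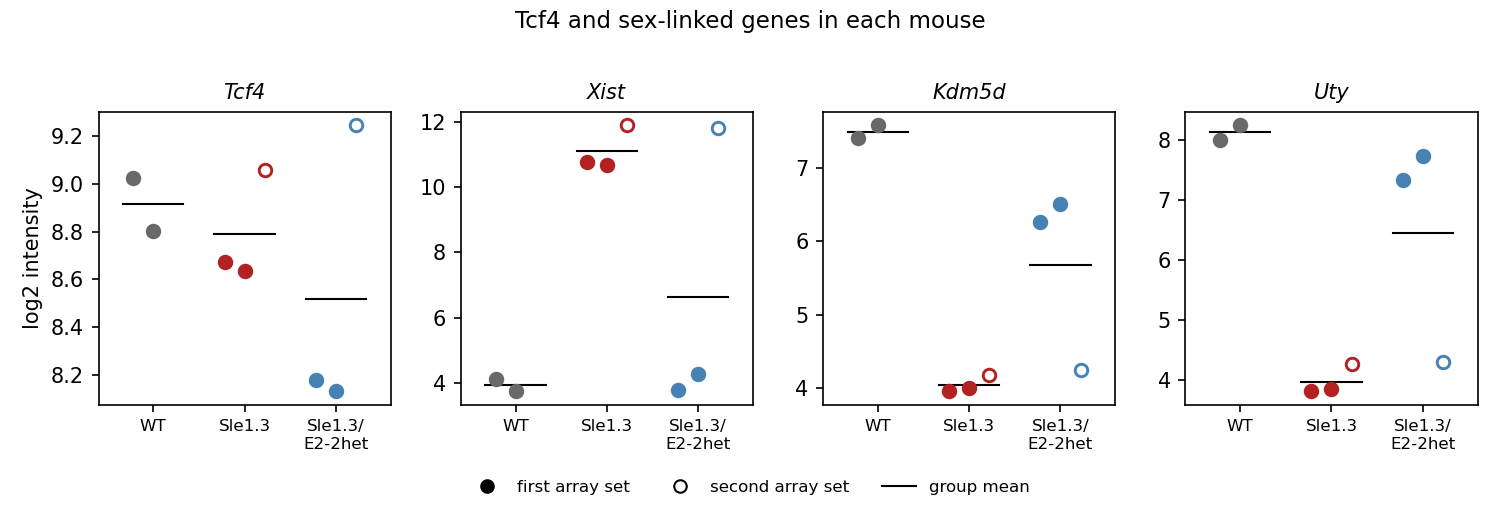
Log2 intensity (vertical axes) of Tcf4, Xist, Kdm5d and Uty in each mouse by genotype, with filled points for the first array set, open points for the second and bars for group means. Tcf4 was lowest in the 2 first-set Sle1.3/E2-2het mice (8.18 and 8.13) and highest in the second-set one (9.25), and Xist was above 10 in all 3 Sle1.3 mice.

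Same-numbered arrays of the Sle1.3 and Sle1.3/E2-2het groups deviated from their group means in like ways, with correlations across genes of 0.573, 0.369 and 0.618 for replicates 1, 2 and 3. Sle1.3 replicate 1 with Sle1.3/E2-2het replicate 2 gave 0.119, and Sle1.3 replicate 2 with Sle1.3/E2-2het replicate 1 gave -0.0194. Genes are not independent replicates, and only the third of the same-numbered pairs is a separate array set. For replicates 1 and 2 a match by chance cannot be excluded. The replicate number is used as a block beside the planned fit, not in its place.

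Sle1.3 spleens, compared with WT to describe the lupus-prone background, had more transcript of granule proteins of developing neutrophils and of cell division genes, and less of natural killer cell genes. These are list calls at the preset correlation, and each had adjusted p = 0.673 with an estimated correlation. Camp, the cathelicidin antimicrobial peptide of neutrophil granules, was 6.87 ± 0.25 (SD, n = 2) in WT and 10.61 ± 1.07 (SD, n = 3) in Sle1.3. Its log2 difference was 4.19 (SE 0.65, adjusted p = 0.0291) in the planned fit, which weights Sle1.3 replicate 3 most, and 3.41 (SE 0.56, adjusted p = 0.00446) in the first set. Mki67, a marker of dividing cells, rose by 1.82 (SE 0.31, adjusted p = 0.0348). Il2rb, a receptor chain for interleukin-2 and interleukin-15 on natural killer and T cells, differed by -1.39 (SE 0.25, adjusted p = 0.0364). In all, 79 genes were higher and 120 lower in limma.

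Of 17 measured neutrophil genes 10 rose and none fell, and 14 rose when adjusted over the list alone. They included Ctsg (4.14, SE 0.75), Ltf (3.99, SE 0.81) and Elane (3.82, SE 0.56), which encode cathepsin G, lactoferrin and neutrophil elastase. The list median was 3.11 (adjusted p = 3.71e-13), and adjusted p = 0.673 with an estimated correlation. Ngp, Prtn3, Lcn2 and the neutrophil surface protein gene Ly6g rose by 3.11 to 3.73. Ear6, an eosinophil-type ribonuclease, rose by 3.30 (SE 0.59, adjusted p = 0.0368). Among 13 monocyte genes 3 rose, also 3 when adjusted over the list alone: the IgG receptor gene Fcgr4 (2.97, SE 0.36, adjusted p = 0.0147), Cd300e (2.04, SE 0.31) and Ms4a6d (2.02, SE 0.33). The monocyte list had a median of 0.77 (adjusted p = 0.00164, and adjusted p = 0.673 with an estimated correlation) and 0.24 in the first set, with 0.70, -0.25 and 1.01 in the 3 Sle1.3 mice. Prss34, a protease of basophils and mast cells, rose by 2.33 (SE 0.41, adjusted p = 0.0352), 1 of 8 measured genes of that list, with 3 when adjusted over the list alone. That list's median was 0.39 (adjusted p = 0.0435, and adjusted p = 0.673 with an estimated correlation) and 0.05 in the first set (adjusted p = 0.205), and it was -0.14 without Sle1.3 replicate 3.

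Of 22 cell cycle genes 9 rose, 18 when adjusted over the list alone, and none fell. Ccna2 (cyclin A2) rose by 1.85 (SE 0.31), Bub1 (a spindle checkpoint kinase) by 1.74 (SE 0.33) and Kif11 (a spindle motor) by 1.73 (SE 0.29). The list median was 1.26 (adjusted p = 4.64e-16, and adjusted p = 0.673 with an estimated correlation). Erythroid genes had a median of 0.68 (adjusted p = 1.98e-04), platelet genes 0.60 (adjusted p = 0.00304) and splenic macrophage genes 0.36 (adjusted p = 0.00403), each with adjusted p = 0.673 with an estimated correlation. In the first set these medians were 0.38, 0.47 and 0.26. In the planned limma fit no member of these 3 lists passed over all genes, and 6 erythroid, 5 platelet and 4 macrophage genes were higher and 1 platelet gene lower at an unadjusted p under 0.05. In the first set 1 erythroid, 4 platelet and 3 macrophage genes were higher and 1 platelet gene lower over all genes. Adjusted over the list alone, 2 erythroid, 3 platelet and 2 macrophage genes were higher in the planned fit. The members with the smallest p were Ppbp, a platelet chemokine (1.72, SE 0.36, adjusted p = 0.0512, and 0.00326 in the first set), and C1qb, a complement subunit made by macrophages (1.77, SE 0.40, adjusted p = 0.0634, and 0.00870 in the first set).

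Natural killer, T and B cell lists went the other way. Of 12 natural killer cell genes 3 fell and 7 fell when adjusted over the list alone: beside Il2rb these were Klrk1, an activating receptor (-1.28, SE 0.24), and Eomes, a transcription factor of cytotoxic lymphocytes (-1.18, SE 0.21). The list median was -0.95 (adjusted p = 3.84e-05, and adjusted p = 0.673 with an estimated correlation) and -0.63 in the first set. T cell genes had a median of -0.38 (adjusted p = 0.00236) with 2 of 14 lower, Lef1 (-1.32, SE 0.27) and Thy1 (-1.12, SE 0.23). In the first set these 2 genes differed by -0.79 and -0.90. In the first set alone the T cell list was not called (median -0.20, adjusted p = 0.0981). B cell genes had a median of -0.31 (adjusted p = 0.0118) with 1 of 15 lower, Fcer2a, the low-affinity IgE receptor (-1.29, SE 0.24). Both lists had adjusted p = 0.673 with an estimated correlation, and 2 T cell genes and 1 B cell gene passed when adjusted over the list alone. Among 18 plasmacytoid dendritic cell genes 2 fell, Spib (-1.76, SE 0.26, adjusted p = 0.0279), an Ets factor also expressed in B cells, and the chemokine receptor gene Ccr9 (-1.26, SE 0.26, adjusted p = 0.0470), 2 also when adjusted over the list alone. That list was not called in the planned fit (median -0.24, adjusted p = 0.0957). Fry with the replicate block called it and the natural killer cell list (adjusted p = 0.0464 each), in a fit that draws partly on the Sle1.3/E2-2het arrays. In the first set alone camera did not call the plasmacytoid dendritic cell list (-0.20, adjusted p = 0.0981) and called the natural killer cell list (adjusted p = 0.00897).

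Interferon-stimulated genes had a median of 0.40 (adjusted p = 0.00562, and adjusted p = 0.673 with an estimated correlation). In the planned limma fit 0 of 33 members passed, over all genes or adjusted over the list alone, with 8 higher and 1 lower at an unadjusted p under 0.05. The 2 members with the smallest p pointed apart, Oas1a, a sensor of double-stranded RNA (0.92, SE 0.23, adjusted p = 0.0808), and Cxcl10, a chemokine (-0.88, SE 0.25, adjusted p = 0.109). In the first set the list median was 0.17 (camera at the preset correlation, adjusted p = 0.00487). There 4 members were higher and 0 lower over all genes. Without Sle1.3 replicate 3 the list median was -0.04. Germinal centre genes were not called as a list (median 0.29, adjusted p = 0.143). Gcsam, a signalling protein of germinal centre B cells, rose by 1.63 (SE 0.30, adjusted p = 0.0372), and Cd86, a costimulatory ligand, fell by 1.57 (SE 0.26, adjusted p = 0.0348). Exocrine pancreas genes, which would come from tissue adhering to the spleen, had a median of 0.37 (adjusted p = 0.0435, and adjusted p = 0.673 with an estimated correlation) with 0 of 7 past the limma test and 2 higher at an unadjusted p under 0.05. That list was not called in the first set (0.20, adjusted p = 0.0542) and was at -0.0705 without Sle1.3 replicate 3. Not called were conventional dendritic cell (-0.15, adjusted p = 0.270), plasma cell (0.22, adjusted p = 0.171), T follicular helper (-0.28, adjusted p = 0.133), stromal (0.26, adjusted p = 0.133), unfolded protein response (0.26, adjusted p = 0.133), dissociation stress (-0.27, adjusted p = 0.270), cytokine (0.0046, mean -0.09, adjusted p = 0.581), antigen presentation (-0.33, adjusted p = 0.280) and Sle1 region genes (0.10, adjusted p = 0.280). In the first set alone plasma cell (0.29, adjusted p = 0.00897) and unfolded protein response genes (0.31, adjusted p = 0.000986) were called. In the planned fit both had adjusted p = 0.741 with an estimated correlation. Fry with the replicate block called T follicular helper and antigen presentation genes (adjusted p = 0.0367 each), in a fit that draws partly on the Sle1.3/E2-2het arrays. In the first set alone camera called neither (-0.23, adjusted p = 0.628, and -0.27, adjusted p = 0.363). Single members of the lists not called in the planned fit passed: Cd209a, a lectin of dendritic cells (-1.92, SE 0.29, adjusted p = 0.0286), Tgfb1, an immunoregulatory cytokine (-1.51, SE 0.24, adjusted p = 0.0294), and Ccl19, a chemokine of T cell zones (1.42, SE 0.27, adjusted p = 0.0382). Fcgr4, given above with the monocyte genes, was also the 1 of 18 Sle1 region genes that was higher.

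Outside the lists, the lower genes with the largest differences included Cpm, encoding carboxypeptidase M (9.72 ± 0.11 in WT and 7.26 ± 0.44 in Sle1.3, SD, log2 difference -2.87, SE 0.27, adjusted p = 0.0101), the kinase gene Plk2 (-2.39, SE 0.25), the phosphodiesterase gene Pde3b (-2.26, SE 0.23) and the glutamine transporter gene Slc1a5 (-2.09, SE 0.24). Others were the microRNA genes Mir142 (-2.42) and Mir18 (-2.22), Sytl3 (-2.23), Ramp3 (-2.21), and the Y-linked Uty (-2.93) and Kdm5d (-2.66). The unnamed transcript G530011O06Rik was higher (2.98, SE 0.36). Xist (4.99, SE 1.77, adjusted p = 0.181) and Eif2s3y (-3.72, SE 0.79, adjusted p = 0.0531) did not pass with labelled sex in the fit.

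At an unadjusted p under 0.05, 2687 genes differed between Sle1.3 and WT, against 748 by chance. In the first set alone 772 were higher and 1595 lower, among which were all 199 planned calls with the same sign. With the array set as a block 796 were higher and 2140 lower, and with the replicate block 1206 and 2965. Both block totals draw partly on the Sle1.3/E2-2het arrays, so they are no separate check of Sle1.3 against WT. Median centring moved the median of the tested genes from 0.03 to -0.12 and gave 311 higher and 1302 lower, while no called list turned its direction. It leaves the spread of each array as it is, and the interquartile range of log2 values was wider in WT (2.77 and 2.97) than in the other arrays (2.41 to 2.57). Quantile normalization, which evens the spread, gave 109 higher and 168 lower. The total of 199 was 106 without Sle1.3 replicate 1, 3645 without Sle1.3 replicate 3, 17, 93 and 4646 without Sle1.3/E2-2het replicates 1, 2 and 3, and 0 in limma without WT replicate 1 or WT replicate 2 (1999 and 1185 genes at an unadjusted p under 0.05).

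Between Sle1.3/E2-2het and Sle1.3, the comparison of interest for the loss of 1 E2-2 copy, no single gene passed the planned test, and most list calls were made at the preset correlation alone. In those lists transcripts of germinal centre B cells, activated T cells, dividing cells and the secretory pathway were lower in Sle1.3/E2-2het mice, and those of natural killer cells, red cell precursors and splenic macrophages were higher. At the preset correlation 16 of 23 lists were called, with 0 at an estimated correlation (smallest adjusted p = 0.101) and 0 with fry. With the replicate block fry called 1 list, that of T follicular helper and activated T cells (adjusted p = 0.0319). Fcgr4, a member of the monocyte and the Sle1 region lists, had the smallest p. It was 9.26 ± 0.52 (SD, n = 3) in Sle1.3 and 6.93 ± 0.36 (SD, n = 3) in Sle1.3/E2-2het, a difference of -2.48 (SE 0.29, adjusted p = 0.0867) with the lower value in 3 of 3 pairs. In limma 0 genes passed in either direction and 392 had an unadjusted p under 0.05, against 748 by chance. The replicate block gave 77 higher and 112 lower genes (72 and 108 on autosomes), the array-set block 22 and 43, and the first set alone 21 and 58, of which 69 were also called with the replicate block in the same direction.

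Germinal centre genes had a median of -0.56 (adjusted p = 2.88e-15, and adjusted p = 0.107 with an estimated correlation), with medians of -0.65 in the first set and -0.41 in the second. In the planned limma fit 0 of the 14 passed over all genes, with 8 lower and 1 higher at an unadjusted p under 0.05. Adjusted over the list alone 7 fell and 1 rose, and with the replicate block 6 fell and 1 rose over all genes, against 3 and 0 in limma both with the array-set block and in the first set alone. Gcsam was 7.89 ± 0.42 (SD, n = 3) in Sle1.3 and 6.23 ± 0.11 (SD, n = 3) in Sle1.3/E2-2het, a difference of -1.66 (SE 0.24, adjusted p = 0.164, and 0.000391 with the replicate block). Mybl1, a transcription factor of germinal centre B cells, differed by -1.95 (SE 0.34, adjusted p = 0.266, and 3.26e-05 with the replicate block). Rgs13, chosen after its values were seen, is a G protein regulator of the same cells and differed by -1.60 (SE 0.39, adjusted p = 0.564, 0.0113 with the replicate block and 0.0883 in the first set). T follicular helper and activated T cell genes had a median of -0.33 (adjusted p = 3.99e-10, and adjusted p = 0.316 with an estimated correlation), -0.43 in the first set and -0.22 in the second, and 0.0709 without Sle1.3 replicate 3. Adjusted over the list alone 4 of these 20 genes fell, and over all genes 7 fell with the replicate block, 3 with the array-set block and 6 in the first set alone. Pdcd1, the inhibitory receptor PD-1, differed by -0.99 (SE 0.24, adjusted p = 0.593), and Gzmk by -0.69 (SE 0.18, adjusted p = 0.697).

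Il10, an immunoregulatory cytokine, was 7.20 ± 0.30 (SD, n = 3) in Sle1.3 and 5.84 ± 0.22 (SD, n = 3) in Sle1.3/E2-2het, a difference of -1.31 (SE 0.22, adjusted p = 0.266). Tnfsf8, the CD30 ligand, differed by -1.46 (SE 0.23, adjusted p = 0.239). Cell cycle genes had a median of -0.50 (adjusted p = 3.47e-23, and adjusted p = 0.176 with an estimated correlation), with 8 of 22 lower when adjusted over the list alone. Over all genes 8 were lower with the replicate block, 2 with the array-set block and 0 in limma in the first set alone, where 6 were lower when adjusted over the list alone. Kif11 differed by -1.10 (SE 0.23, adjusted p = 0.402) and Top2a, a DNA topoisomerase, by -0.92 (SE 0.21, adjusted p = 0.513). Unfolded protein response genes had a median of -0.39 (adjusted p = 1.69e-13, and adjusted p = 0.176 with an estimated correlation). In that list, at -0.63 in the first set and -0.19 in the second, 1 of 18 genes was lower when adjusted over the list alone and 1 over all genes with either block or in the first set. Adjusted over the list alone, 11 were lower with the replicate block, 9 with the array-set block and 15 in the first set. The members with the smallest p were the endoplasmic reticulum genes Creld2 (-0.96, SE 0.22, adjusted p = 0.478) and Hsp90b1 (-0.68, SE 0.21, adjusted p = 0.974). Plasma cell genes had a median of -0.11 (adjusted p = 0.00223, and adjusted p = 0.585 with an estimated correlation), -0.53 in the first set and -0.04 in the second, and 0.35 without Sle1.3 replicate 3. Mzb1, a chaperone of antibody-secreting cells, differed by -0.78 (SE 0.19, adjusted p = 0.593).

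Natural killer cell genes had a median of 0.79 (adjusted p = 3.47e-23, and adjusted p = 0.101 with an estimated correlation), 0.52 in the first set and 0.93 in the second. Of the 12 genes 8 rose when adjusted over the list alone. Over all genes 8 rose with the replicate block, 3 with the array-set block and 1 in the first set alone. Gzma and Gzmb, which encode granzymes of cytotoxic granules, differed by 1.29 (SE 0.23, adjusted p = 0.266) and 1.10 (SE 0.23, adjusted p = 0.402). Il12rb2, a subunit of the interleukin-12 receptor, differed by 1.19 (SE 0.18, adjusted p = 0.239). Erythroid genes had a median of 0.80 (adjusted p = 3.30e-23, and adjusted p = 0.107 with an estimated correlation), 1.34 in the first set and 0.33 in the second, with 7 of 13 higher when adjusted over the list alone. Over all genes 8 rose with the replicate block, 1 with the array-set block and 6 in the first set alone. Slc4a1, the anion exchanger of the red cell membrane, was 7.07 ± 0.84 (SD, n = 3) in Sle1.3 and 9.32 ± 0.41 (SD, n = 3) in Sle1.3/E2-2het, a difference of 2.03 (SE 0.36, adjusted p = 0.266). Alas2, the erythroid enzyme of haem synthesis, differed by 2.09 (SE 0.46, adjusted p = 0.478). Splenic macrophage genes had a median of 0.33 (adjusted p = 1.87e-09, and adjusted p = 0.176 with an estimated correlation). The list was at 0.51 in the first set and 0.16 in the second. Adjusted over the list alone 5 of 16 rose, and over all genes 3 with the replicate block and 1 each with the array-set block and in the first set. Slc40a1, the iron exporter ferroportin, differed by 1.19 (SE 0.29, adjusted p = 0.564) and Vcam1, an adhesion molecule, by 1.03 (SE 0.25, adjusted p = 0.564). Cd209a differed by 1.65 (SE 0.23, adjusted p = 0.164, and 0.000213 with the replicate block) and the ubiquitin ligase gene Trim13 by 1.48 (SE 0.26, adjusted p = 0.266).

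**Figure D2:**
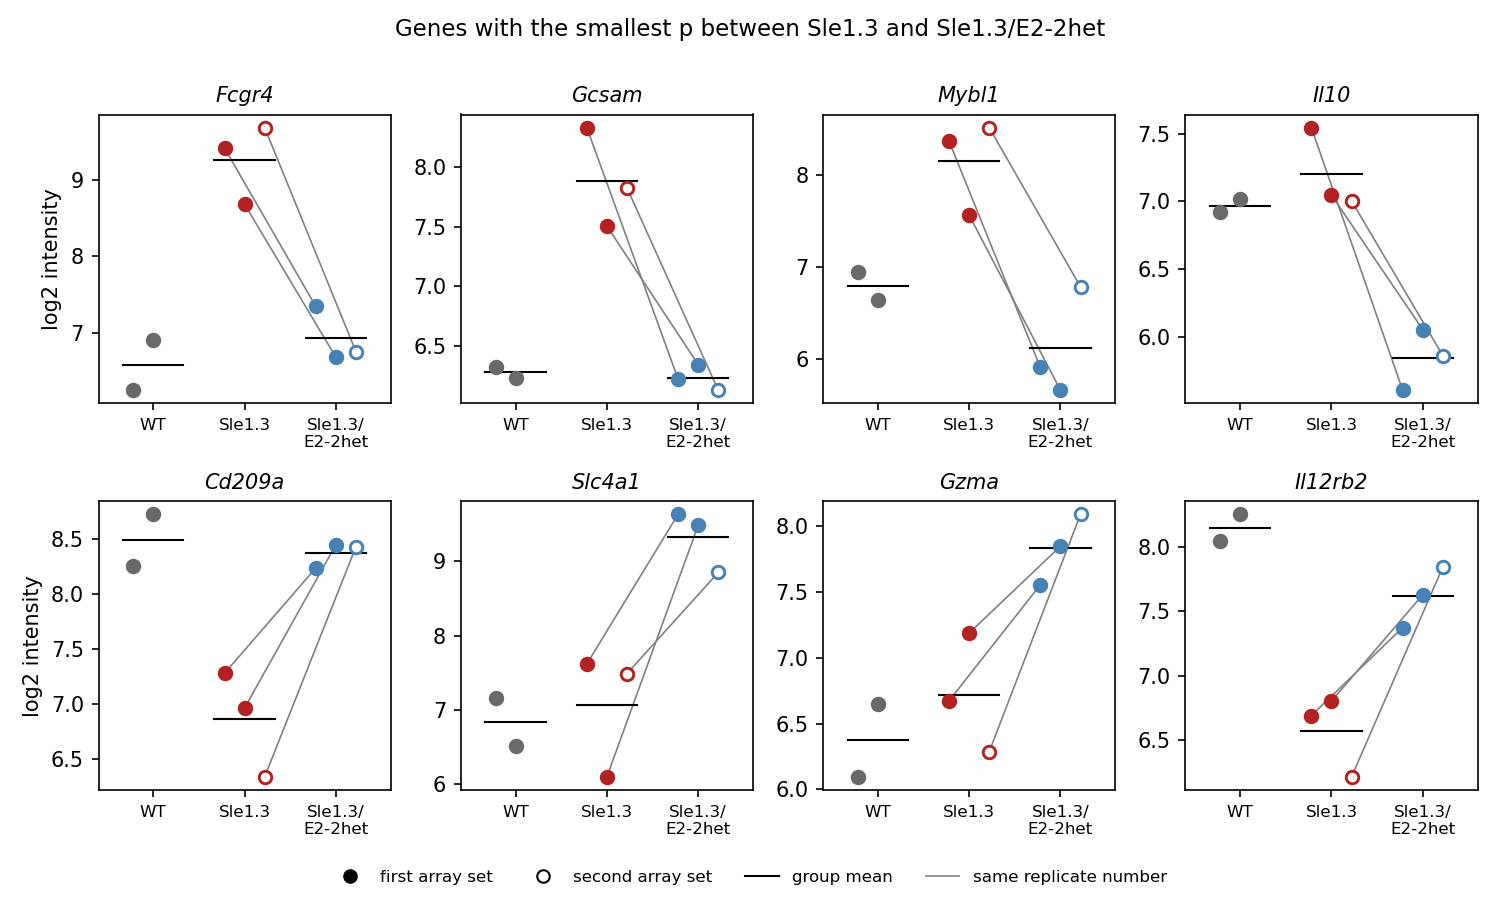
Log2 intensity (vertical axes) of 8 genes in each mouse by genotype, with lines joining Sle1.3/E2-2het and Sle1.3 mice of the same replicate number, filled points for the first array set, open points for the second and bars for group means. Fcgr4, Gcsam, Mybl1 and Il10 were lower in the Sle1.3/E2-2het mouse of all 3 pairs, and Cd209a, Slc4a1, Gzma and Il12rb2 were higher in all 3.

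Plasmacytoid dendritic cell genes, the cells that depend on E2-2, were not called as a list (median 0.04, mean -0.02, adjusted p = 0.820). In limma 0 of 18 passed over all genes and 1 was lower when adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05. With the replicate block 1 was higher and 1 lower, and 1 was lower with the array-set block and in the first set. The members with the smallest p were Havcr1 (-1.21, SE 0.22, adjusted p = 0.266) and Klra17 (-0.72, SE 0.21, adjusted p = 0.914), and Spib differed by -0.08 (SE 0.21, adjusted p = 1.00). Interferon-stimulated genes had a median of -0.19 (adjusted p = 3.03e-06, and adjusted p = 0.431 with an estimated correlation), -0.22 in the first set and -0.23 in the second, and 0.08 without Sle1.3 replicate 3. In limma 0 of 33 passed over all genes or over the list alone, and 3 were lower at an unadjusted p under 0.05. The replicate block gave 0 over all genes, and 5 lower and 1 higher when adjusted over the list alone. Parp14 differed by -0.57 (SE 0.20, adjusted p = 1.00) and Xaf1 by -0.45 (SE 0.18, adjusted p = 1.00).

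Neutrophil genes had a median of -0.57 (adjusted p = 1.21e-04, and adjusted p = 0.585 with an estimated correlation), -0.07 in the first set and -1.19 in the second, with 5 of 17 lower with the replicate block and 0 in limma with the array-set block or in the first set. Monocyte genes had a median of -0.02 (adjusted p = 0.00651, and adjusted p = 0.585 with an estimated correlation), 0.33 in the first set and -0.25 in the second. T cell genes had a median of 0.04 (adjusted p = 0.0185, and adjusted p = 0.590 with an estimated correlation), -0.18 and 0.29. Platelet genes had a median of -0.12 (adjusted p = 0.00189, and adjusted p = 0.431 with an estimated correlation), Sle1 region genes -0.14 (adjusted p = 5.62e-04, and adjusted p = 0.536 with an estimated correlation), antigen presentation genes -0.08 (adjusted p = 0.00651, and adjusted p = 0.585 with an estimated correlation) and conventional dendritic cell genes 0.08 (adjusted p = 0.0347, and adjusted p = 0.585 with an estimated correlation). In the first set alone the neutrophil, monocyte, T cell, platelet and conventional dendritic cell lists were not called (adjusted p = 0.683, 0.842, 0.0933, 0.0759 and 0.191). Without Sle1.3 replicate 3 the platelet, Sle1 region and antigen presentation medians were 0.0338, 0.14 and 0.25, and the monocyte median was 0.21. Monocyte genes were also at 0.22 without Sle1.3 replicate 1 and 0.0889 without Sle1.3/E2-2het replicate 2, and T cell genes at -0.11 without Sle1.3 replicate 1. Without Sle1.3/E2-2het replicate 3 the T cell and conventional dendritic cell medians were -0.22 and -0.12. Not called were B cell (0.03, adjusted p = 0.764), mast cell and basophil (-0.11, adjusted p = 0.0767), stromal (0.00042, mean -0.04, adjusted p = 0.834), exocrine pancreas (0.09, adjusted p = 0.724), dissociation stress (0.06, mean -0.03, adjusted p = 0.798) and cytokine genes (0.10, adjusted p = 0.259). Of these the first set called B cell (-0.20, adjusted p = 0.0147) and dissociation stress genes (-0.16, adjusted p = 0.0317). In the planned fit both had adjusted p = 0.908 with an estimated correlation.

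The total of 0 genes for Sle1.3/E2-2het versus Sle1.3 was 3 without Sle1.3 replicate 1, 4 without Sle1.3 replicate 2, 3 without Sle1.3/E2-2het replicate 1, 1602 without Sle1.3 replicate 3 and 2114 without Sle1.3/E2-2het replicate 3. Omitting either array of the second set leaves the other as the only array that separates the labelled sexes within the Sle1.3 groups, so its set difference is then taken for a sex difference.

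**Figure D3:**
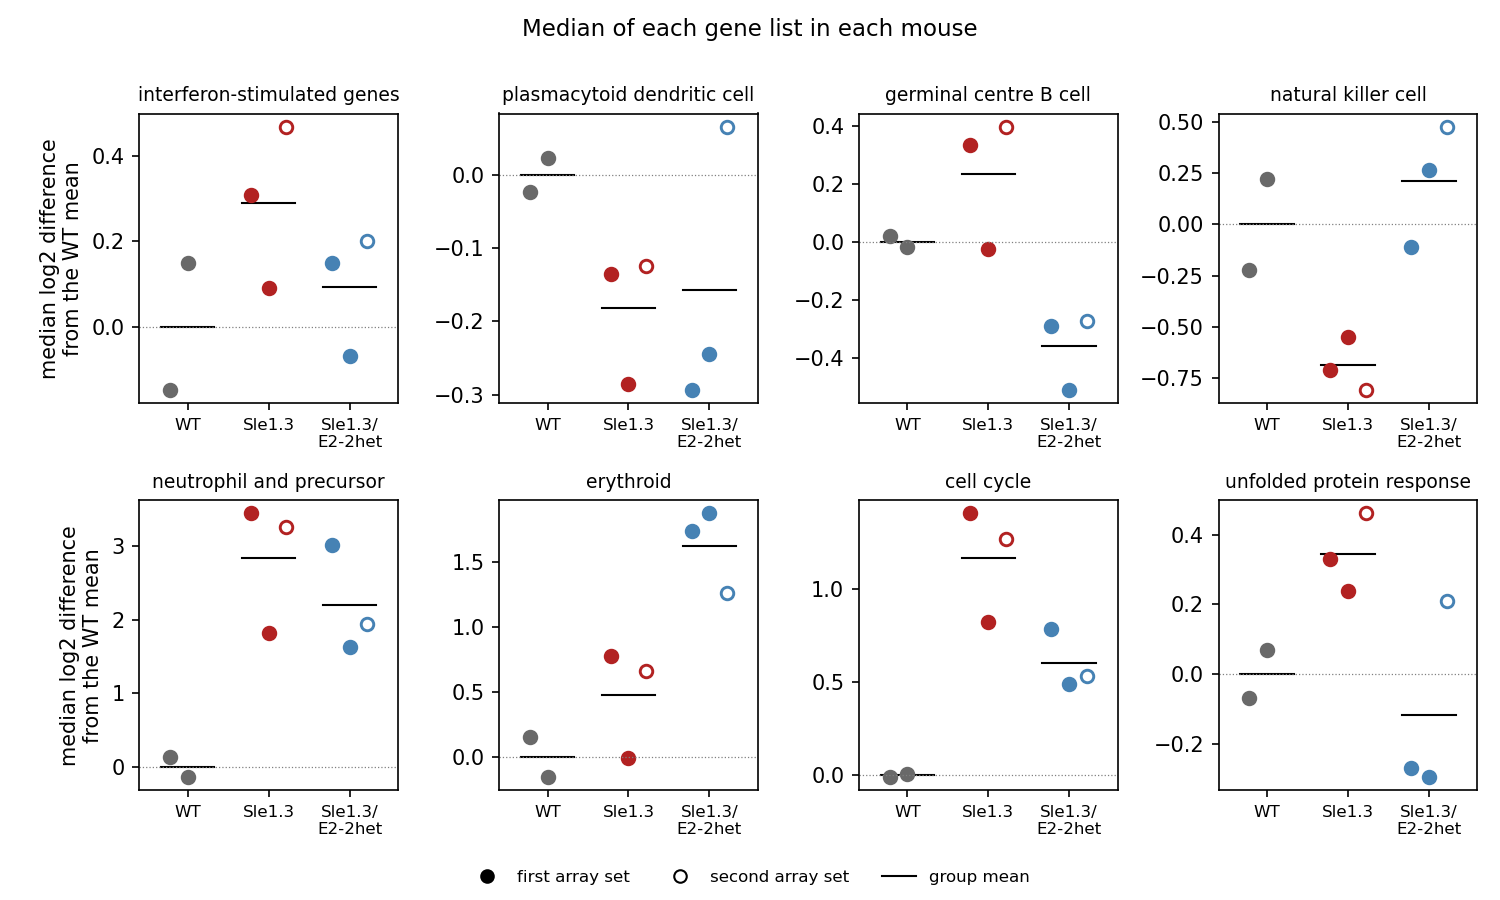
Median log2 difference from the WT mean (vertical axes) of the members of 8 gene lists in each mouse by genotype, with filled points for the first array set, open points for the second and bars for group means. The erythroid list lay at 1.74, 1.88 and 1.26 in the Sle1.3/E2-2het mice and at 0.78, -0.01 and 0.66 in the Sle1.3 mice, and the natural killer cell list at -0.71, -0.55 and -0.81 in the Sle1.3 mice.

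Sle1.3/E2-2het spleens, compared with WT, had more transcript of neutrophil granules, red cell precursors and splenic macrophages, and less of activated T cell genes. These are list calls at the preset correlation, with adjusted p = 0.646 (red cell precursors, macrophages) and 0.719 (neutrophils, activated T cells) with an estimated correlation. Camp rose by 3.49 (SE 0.58, adjusted p = 0.0223), with 10.13 ± 0.88 (SD, n = 3) in Sle1.3/E2-2het. Slc4a1 rose by 2.70 (SE 0.40, adjusted p = 0.0158), with 6.84 ± 0.45 (SD, n = 2) in WT and 9.32 ± 0.41 (SD, n = 3) in Sle1.3/E2-2het. Gzmk, a granzyme of T cells, fell by 1.33 (SE 0.20, adjusted p = 0.0174). In limma 256 genes were higher and 236 lower, and 3887 had an unadjusted p under 0.05, against 748 by chance.

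Of 13 erythroid genes 9 rose and 12 rose when adjusted over the list alone, among them Rhag, a Rh-associated membrane protein (2.63, SE 0.50), Alas2 (2.55, SE 0.51) and Car1, a carbonic anhydrase (2.79, SE 0.61). The list median was 1.75 (adjusted p = 4.57e-11, and adjusted p = 0.646 with an estimated correlation). Of 16 splenic macrophage genes 3 rose and 9 rose when adjusted over the list alone: Slc40a1 (1.77, SE 0.32), the lectin gene Fcna (1.27, SE 0.28) and Vcam1 (1.21, SE 0.28). That median was 1.02 (adjusted p = 1.48e-07, and adjusted p = 0.646 with an estimated correlation). Of 17 neutrophil genes 8 rose and 14 rose when adjusted over the list alone, including Ltf (3.23, SE 0.72), Ngp (3.09, SE 0.66) and S100a8, a calprotectin subunit (2.74, SE 0.52). The median was 2.51 (adjusted p = 1.61e-10, and adjusted p = 0.719 with an estimated correlation). Cell cycle genes had a median of 0.67 (adjusted p = 8.30e-07, and adjusted p = 0.719 with an estimated correlation). Of these 22 genes 3 rose and 11 rose when adjusted over the list alone, with Rrm2 (1.29, SE 0.22) and Tyms (1.03, SE 0.21), enzymes of nucleotide synthesis, and Ccna2 (1.28, SE 0.28).

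T follicular helper and activated T cell genes had a median of -0.66 (adjusted p = 1.06e-04, and adjusted p = 0.719 with an estimated correlation), with 2 of 20 lower and 10 when adjusted over the list alone. Beside Gzmk this was Il2ra, the interleukin-2 receptor alpha chain (-1.02, SE 0.23). B cell genes had a median of -0.39 (adjusted p = 0.0289, and adjusted p = 0.719 with an estimated correlation), with 0 of 15 past the limma test, 5 lower at an unadjusted p under 0.05 and 3 lower when adjusted over the list alone. Monocyte genes had a median of 0.55 (adjusted p = 0.0272) and exocrine pancreas genes of 0.46 (adjusted p = 0.0364), both with adjusted p = 0.719 with an estimated correlation. In limma 0 members of either list passed, with 5 and 2 higher at an unadjusted p under 0.05. Natural killer cell genes were not called (median 0.08, adjusted p = 0.966), with Gzma higher (1.29, SE 0.26, adjusted p = 0.0342) and Il2rb (-1.12, SE 0.22) and Eomes (-1.01, SE 0.19) lower. Nor were interferon-stimulated genes (median 0.10, adjusted p = 0.350), of which Rsad2, the antiviral enzyme viperin, rose by 1.97 (SE 0.45, adjusted p = 0.0465) and Cxcl10 fell by 1.03 (SE 0.22, adjusted p = 0.0397). Plasmacytoid dendritic cell genes had a median of -0.19 (adjusted p = 0.0940) with Spib lower (-1.84, SE 0.23, adjusted p = 0.0138). Il10 (-1.18, SE 0.24) and Tgfb1 (-1.16, SE 0.21) fell, Ccl19 rose by 1.42 (SE 0.24), and Cr1l, a complement regulator of the Sle1 region list, fell by 1.14 (SE 0.22). Germinal centre, T cell and antigen presentation genes had medians of -0.36, -0.28 and -0.41, each with adjusted p = 0.0512. T cell (-0.42, adjusted p = 0.0259) and antigen presentation genes (-0.62, adjusted p = 0.0137) were called in the first set. In the planned fit both had adjusted p = 0.719 with an estimated correlation. Fry with the replicate block called antigen presentation (adjusted p = 0.0108) and T follicular helper genes (adjusted p = 0.00930). The other lists ranged from -0.21 to 0.43 and were not called.

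Outside the lists, Tmem267 (2.76, SE 0.23, adjusted p = 0.00319) and the carbonic anhydrase gene Car2 (2.89, SE 0.52, adjusted p = 0.0258) were higher. Cpm (-2.43, SE 0.24, adjusted p = 0.00333), Plk2 (-2.43, SE 0.22), Mir142 (-2.41, SE 0.27), Slc1a5 (-2.07, SE 0.21) and the opioid precursor gene Penk (-1.89, SE 0.27) were lower. Tcf4 differed by -0.51 (SE 0.32, adjusted p = 0.323) in the planned fit and by -0.76 (SE 0.15, adjusted p = 0.00551) in the first set, where both groups were male by Xist.

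For Sle1.3/E2-2het versus WT, the array-set block by construction repeats the first set alone, as does omitting either second-set array. That gave 1581 higher and 3505 lower genes. All 492 planned calls were among them with the same sign, but they rest largely on the same arrays. The replicate block gave 2034 and 4225. Median centring moved the median of the tested genes from -0.01 to -0.19 and the calls to 648 higher and 3132 lower. Quantile normalization, which also evens the wider spread of the WT arrays, gave 322 higher and 441 lower. The total of 492 was 272 without Sle1.3 replicate 2, 5086 without Sle1.3 replicate 3, 18, 23 and 5086 without Sle1.3/E2-2het replicates 1, 2 and 3, and 0 in limma without WT replicate 1 or WT replicate 2 (2764 and 1540 genes at an unadjusted p under 0.05).

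Among the 199 genes called between Sle1.3 and WT, 154 (77.4%) had the opposite sign between Sle1.3/E2-2het and Sle1.3. The Sle1.3 arrays and, through the labelled-sex term, the Sle1.3/E2-2het arrays enter both differences. For that reason simulated arrays without any group effect gave 93.4%, and the correlation of the differences across genes was -0.178 against -0.534 in 100 simulations. With the replicate block, 2231 of 4171 called genes (53.5%) had the opposite sign, against 82.2% in simulated arrays, and the correlation was -0.168 against -0.516. The covariance was -0.0198 against -0.0372 simulated in the planned fit, and -0.0181 against -0.0128 with the block. In that fit 102 genes were called in both comparisons with opposite signs and 24 with the same sign. Independent calls would give 24.3 and 28.4, a reference that leaves out the shared arrays. Gcsam and Fcgr4 were among the 102 with the block, higher in Sle1.3 than in WT and lower in Sle1.3/E2-2het than in Sle1.3. Sle1.3 replicates 1 and 2 against WT and Sle1.3 replicate 3 against Sle1.3/E2-2het replicate 3 share no array. That division leaves 1 array per group in the second difference, and a reversal was not tested with it. Shares and correlations lay below the simulated size and the block covariance above it. The simulated arrays hold noise alone, while called genes also differ from WT, so a share below theirs does not speak against a reversal. A reversal beyond the shared arrays was therefore not settled.

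By chromosome, 18 of 516 tested genes of chromosome 13 were called between Sle1.3 and WT (odds ratio 2.87, Fisher's exact test, adjusted p = 0.00378), among them Plk2, Tmem267, Serpinb9, a granzyme inhibitor gene, and the histone genes H1f1, H1f5, H2ac4, H2bc3 and H4c6. Without olfactory and vomeronasal receptor genes it was 17 of 504 (odds ratio 2.93, exact p = 2.04e-04). With the replicate block the adjusted p was 0.0962. On chromosome Y, 2 of 5 genes were called (adjusted p = 0.0186, exact test), and the adjusted p was 0.124 with the replicate block. Between Sle1.3/E2-2het and WT, 71 of 1239 genes of chromosome 2 were called (odds ratio 1.93, exact test, adjusted p = 7.75e-05). With the replicate block the odds ratio was 1.08 and the adjusted p 0.362. Of the 71, 46 were olfactory receptor genes, and without such receptors 25 of 1140 were called (odds ratio 0.865, exact p = 0.553). Chromosome 1 showed no excess between Sle1.3 and WT, with 10 of 867 called (odds ratio 0.864, exact p = 0.760). Between Sle1.3/E2-2het and Sle1.3 the replicate block called 5 of 341 genes of chromosome 18, which holds Tcf4 (odds ratio 1.16, exact p = 0.624). Only chromosome Y passed there, with 4 of 5 (exact test, adjusted p = 2.73e-06).

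The interaction of labelled sex with genotype within the Sle1.3 background, fitted with 3 residual degrees of freedom, passed for 5118 of 14953 genes, with 7008 at an unadjusted p under 0.05. Labelled sex changes with the array set in both genotypes, and the interaction is the difference between the second set and the first. This labelled-sex term cannot be told apart from the array set. All 3 Sle1.3 mice were female by Xist, so it does not measure an interaction of sex with genotype.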

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

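The test of Tcf4 between the array sets, the 4 tests of its second-set value and the scale test of the second set were chosen only after the results were seen.

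In the second array set Tcf4 was 0.19 higher in the Sle1.3/E2-2het mouse (9.25) than in the Sle1.3 mouse (9.06), while in the first set both Sle1.3/E2-2het mice (8.18 and 8.13) lay below both Sle1.3 mice (8.67 and 8.63). The distance of 0.69 between the set differences (SE 0.26) had an unadjusted p = 0.0245 in limma and adjusted p = 0.997 over all genes. Swapped labels of the 2 arrays would reverse the other genes too, but the second-set difference correlated at 0.0753 to 0.40 with the 4 single-mouse differences of the first set, and compressed signal is argued against by interquartile ranges of the second-set arrays at 1.01 times those of the first set. A mouse like Sle1.3 in place of the labelled one would keep the sign of the first-set differences by chance, but 100% of 69 autosomal genes called in the first set had the same sign in the second, against 52.3% of all 14497. Lower Tcf4 in males is argued against by the first-set difference of -0.76 (SE 0.15) between Sle1.3/E2-2het and WT mice, all male by Xist, and what stays open, untested, is chance in a single mouse, a probe set that may not cover the changed part of Tcf4, and an effect of sex within the Sle1.3 background.

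Sle1.3 replicate 3 and Sle1.3/E2-2het replicate 3 resembled each other more than their own groups, with deviations from the group means that correlated at 0.618 across genes. A difference of scale alone between the sets is argued against by a correlation of 0.677 after quantile normalization. Spleens prepared or arrays run on another day could give such a pattern, as could age, litter or housing of the mice. No label gives any of these, and no biological explanation was tested.

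The interaction term of labelled sex with genotype passed for 5118 of 14953 genes within the Sle1.3 background. It is a difference between groups that has the array set as its other name, since labelled sex changes with the set in both genotypes. All 3 Sle1.3 mice were female by Xist, so this term does not measure an interaction of sex with genotype. Among 9209 probe sets that stand for several genes or for none, data outside the comparisons, 567 passed the threshold between Sle1.3 and WT, 413 higher and 154 lower.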

How the results depend on the processing

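The 4 settings that use the array set were chosen after seeing the data, as were the tests made with them. Across all settings, the lists kept direction and side of the threshold in 528 instances for Sle1.3 versus WT (23 stronger, 66 weaker, 3 reversed), 522 for Sle1.3/E2-2het versus Sle1.3 (6, 65 and 27) and 528 for Sle1.3/E2-2het versus WT (63 stronger, 29 weaker). Named genes did so in 1147 (219 stronger, 224 weaker, 1 reversed), 1329 (311 stronger, 1 reversed) and 1225 instances (303 stronger, 186 weaker). Totals of genes called stayed within 1.5 times the planned total in 5, 9 and 5 settings and moved in 20, 16 and 20. Planned totals were 199, 0 and 492 in that order of comparisons, which is kept below. Without the sex covariate they were 879, 2 and 1076, with the replicate block 4171, 189 and 6259, and with that block without sex 4410, 262 and 6008. Among mice labelled male they were 4336, 1861 and 4767, but there the Sle1.3 arm is 1 array, of the second set and female by Xist, so the first and second of these totals are no comparison within males. With only the groups compared they were 4710 and 4767 for the comparisons with WT, which by construction rest on the mice labelled male, and so on Sle1.3 replicate 3 alone in the first. The array-set block gave 2936, 65 and 5086 with labelled sex, 456, 1 and 5086 with sex read from Xist and the Y-linked genes, and 2229, 89 and 2780 with quantile normalization and no sex. With sex so read, Sle1.3/E2-2het versus Sle1.3 by construction rests on the second-set pair alone, 1 array each, and Tcf4 differed by 0.19. Sle1.3 versus WT is then the first-set difference of Sle1.3/E2-2het from WT minus that pair's difference. It uses neither Sle1.3 replicate 1 nor Sle1.3 replicate 2. The totals of 456 and 1 are therefore no result corrected for sex. The first set alone gave 2367, 79 and 5086. Median centring gave 1613, 2 and 3780, quantile normalization 2 and 763 for the comparisons of Sle1.3/E2-2het with Sle1.3 and with WT, and a mean above the 50th percentile 309 and 3 for the first and second comparison. With no filter on dim genes, which adds tests, the totals against WT were 12 and 66. Array weights, whose estimation stopped before it converged, gave 0 in limma for Sle1.3 versus WT (658 genes at an unadjusted p under 0.05) and 5979 for Sle1.3/E2-2het versus WT.

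Leaving out each mouse gave totals of 0 to 4646, 0 to 2114 and 0 to 5086. Omitting a WT mouse leaves 1, which is then assumed to vary like the other groups. Omitting either second-set array leaves the other to carry the labelled sex by construction, and this gave the extremes of Tcf4 between Sle1.3/E2-2het and Sle1.3 (-0.90 to 0.59), of Xist (-7.86 to 1.09 there and -0.98 to 7.97 for Sle1.3 versus WT) and of most list medians below. Tcf4 was -0.90 among mice labelled male (adjusted p = 0.0187), which sets first-set males against that 1 second-set array, and its adjusted p ranged up to 1.00 over the settings. Interferon-stimulated genes in Sle1.3 versus WT ranged from -0.0358 to 0.50 and lost the call at 0.40 with an estimated correlation (p = 0.673), with fry (0.40, p = 0.409) and with no filter (0.40, p = 0.0553), and at 0.47 with only the groups compared (p = 0.0617). Between Sle1.3/E2-2het and Sle1.3 they ranged from -0.51 to 0.0772 and lost the call at -0.19 with an estimated correlation (p = 0.431) and fry (p = 0.653), and at -0.51 among mice labelled male (p = 0.140).

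Other lists also reversed between Sle1.3/E2-2het and Sle1.3. T cell genes were at -0.0384 without the sex covariate and with the block without sex, at -0.0446 with array weights, at -0.18 in the first set, -0.22 among mice labelled male, -0.00508 above the 50th percentile and -0.00824 with quantile normalization and the array-set block. Monocyte genes were at 0.13 without the sex covariate and with the block without sex, 0.19 with array weights, 0.33 in the first set and 0.16 with quantile normalization and the array-set block. Conventional dendritic cell genes were at -0.12 among mice labelled male, and in the first set B cell genes at -0.20 and dissociation stress genes at -0.16. Leaving out each mouse gave T cell -0.22 to 0.48, monocyte -0.35 to 0.22, conventional dendritic cell -0.12 to 0.41, Sle1 region -0.45 to 0.14, T follicular helper -0.61 to 0.0709, antigen presentation -0.47 to 0.25, platelet -0.52 to 0.0338 and plasma cell genes -0.64 to 0.35. For Sle1.3 versus WT it gave exocrine pancreas -0.0705 to 0.63 and mast cell and basophil genes -0.14 to 0.73. Apart from the construction named above, the cause was not tested. With 2 or 3 arrays per group and no background level in the table, small differences of dim genes cannot be resolved.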

Other observations

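The scale test of the receptor genes and the genes named first below were chosen only after their values were seen, and the tests on dim genes and on other splits were not.

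Outside the naming rule, further genes passed the replicate-block fit between Sle1.3/E2-2het and Sle1.3, each chosen after its values were seen. No list or enrichment test stands behind them, and they describe no class of genes. The small nucleolar RNA genes Snora44 and Snord118 were higher, Snora44 at 1.67 (SE 0.19, adjusted p = 0.000879) and Snord118 at 1.55 (SE 0.24, adjusted p = 0.00694), each with adjusted p = 0.0158 in the first set alone. Snora75 (1.47, SE 0.27, adjusted p = 0.0155, and 0.358 in the first set) was also higher, as were Ncr1, an activating receptor of natural killer cells (1.48, SE 0.16, adjusted p = 0.000643, and 0.391 in the first set) and the interferon-induced membrane protein gene Ifitm1 (1.53, SE 0.23, adjusted p = 0.00610, and 0.534 in the first set). The granule protein genes lower with the block were Ear6 (-1.89, SE 0.24, adjusted p = 0.00163), Prg2 (-1.54, SE 0.19, adjusted p = 0.00154), Mcpt8 (-1.54, SE 0.26, adjusted p = 0.0113), Mpo (-1.50, SE 0.25, adjusted p = 0.0107) and Ctsg (-1.46, SE 0.22, adjusted p = 0.00566), none of which passed in the first set (adjusted p from 0.373 to 0.695). Sostdc1, a secreted antagonist of bone morphogenetic proteins (-1.84, SE 0.15, adjusted p = 7.98e-05, and 0.00117 in the first set), and the protease gene Adamdec1 (-1.47, SE 0.21, adjusted p = 0.00396, and 0.177 in the first set) were lower too. None of these passed the planned fit, where Snora44 had adjusted p = 0.266 and Ctsg adjusted p = 1.00.

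Olfactory and vomeronasal receptor genes read higher in Sle1.3 than in WT. Over 1194 such genes the median difference was 0.71, against 0.18 for all genes, and the median per mouse was at most 4.16 in WT and 4.70, 4.63 and 5.21 in Sle1.3. A difference of scale alone between arrays is argued against by a gap of 0.409 to all genes after quantile normalization, and a shift of dim genes in general by a gap of 0.350 to genes matched on mean intensity, whose median was 0.36 and lay between 0.346 and 0.370 in 1000 draws. Such receptors made up 16 of the 79 genes called higher, so part of that count may stem from a shared property of their probes, such as base composition, that was not tested.

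For Sle1.3/E2-2het versus Sle1.3, the 6 mice can be split in too few ways for a share under 0.05. The planned fit gave 0 genes in the real split and up to 8 in another. All 9 of 9 estimable splits were as large, which a real count of 0 fixes in advance, so this decides nothing. The planned fit also gave 16 gene lists in the real split and up to 16 in another, with 2 of 9 as large. With the replicate block and no sex, the real split gave 262 genes and the highest of the others that part all 3 pairs gave 0, which is 1 of 4.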
